A study of Homo sapiens with 9 samples.

How the data were processed

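Poly(A)-selected RNA sequencing libraries of cells labelled BxPC3 were examined in 9 samples, 3 each for vehicle (DMSO), MS172 and PK9328. Group and replicate number were taken from the sample titles. The treatment protocol in the labels gives 5 µM for 6 h, but it names PK9328 and MS78, whereas titles, treatment labels and the series design name MS172. The groups are called by their titles here, and the dose and time of MS172 are those of a protocol that uses another compound name. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

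The deposited tables hold, per the file headers, the length, effective length, TPM and estimated count of reads of 197653 transcripts in each library, and the estimated counts need not be whole numbers. The TPM values were normalised by the authors to transcript length and to a total of 1000000 per library, per the file headers. The submitters' processing notes name FastQC 0.11.8 and the genome build hg38. The quantification program, its version and the release of its transcript index are not given in the sources used here.

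Transcripts were matched by identifier, without the version, to GENCODE 29, and 193505 of 197653 matched. The unmatched transcripts held 0.356% to 0.382% of the estimated reads of a library and were left out. The estimated counts of the matched transcripts were summed for 56865 genes and rounded to whole numbers. Totals were 24077353 to 28031886 estimated reads per library. Coordinates are those of GENCODE 29 on GRCh38, counted from 1. Reads that near-identical genes share had been split by the authors' quantification, so single values of metallothionein, HSPA1A and HSPA1B, NBPF and readthrough or overlapping genes (MIA-RAB4B, FSBP) are uncertain, as are those of antisense partners.

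Each comparison used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with robust dispersion estimates, TMM normalisation and filterByExpr by group. All 9 libraries entered a single fit without a replicate term, which left 6 residual degrees of freedom. Of the summed genes, 13914 passed the filter, and genes with a Benjamini-Hochberg adjusted p under 0.05 are said to rise, fall or change. The common biological coefficient of variation was 0.044. Standard errors were derived from the fold change and its F statistic, and intervals are 95% intervals. CPM values use TMM-scaled library sizes and are given as the mean ± SD of 3 libraries. These intervals and errors cover the spread between the libraries, not unmeasured variation between cultures.

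The tests, the gene lists and the rule for named genes were fixed before the data were examined. In each comparison the rule took coding genes past the threshold with at least 1 CPM over all 9 libraries and no overlap between the groups, namely the 8 largest rises, the 8 largest falls and the 4 smallest p-values not already taken. It added genes whatever their result, among them CDKN1A, MDM2, BBC3, GDF15, CYP1A1, HMOX1, MYC, FOS, EGR1, EP300 and CREBBP, and up to 4 members of each list with the smallest p. Some genes that the rule names are not reported here. Other list members are cited as examples chosen after their values were seen. Of 29 lists, 27 had at least 2 members past the filter and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, with adjustment over 81 tests. Of 44 calls, 26 held with an estimated correlation. The camera p-values below use the preset unless an estimated correlation is named, and the estimated one gave larger values for these 26. The acinar and endocrine list had no member past the filter, with a highest value of 0.0393 CPM in any library, and the endothelial list had 1.

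Alternatives planned beforehand were RLE size factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, counts rebuilt from length-scaled TPM, a fit of only the libraries compared, other list tests and each library left out in turn. Other settings were added after seeing the data. They are fragment length as a covariate, an offset for each library's trend with GC content and transcript length (mgcv 1.9.3), and log CPM differences with a prior count of 2 in place of edgeR fold changes for the shared response. The offset was first built so that the trend also set each library's level. The centred form, in which TMM sets the level, was made after the balance of higher and lower calls under the first form had been seen, and both forms are reported. The log CPM differences were tried after the correlation of edgeR fold changes had been seen, and the edgeR values remain the reported ones. Unchanged groups were simulated again for the stricter filter, the covariate and each library left out, which was added after those correlations had been seen.

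Fragment length was read as transcript length minus effective length over transcripts of at least 3000 bases. The fits were tested on simulated data drawn from the real means and library sizes. These data held far fewer changed genes than the real comparisons, so the shares recovered do not carry over. For MS172 against DMSO, 46% of genes changed 1.2-fold, 73.5% of those changed 1.5-fold, 80% of those changed 2-fold and 100% of those changed 4-fold were recovered among 13722 genes tested, with 12 false calls in 160. No replicate pair was a duplicate library, since the chi-square per degree of freedom between libraries of a group was 3.39 to 7.11.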

Results

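Cells labelled BxPC3, a human pancreatic adenocarcinoma cell line, were treated with vehicle (DMSO), MS172 or PK9328, and poly(A)-selected RNA was sequenced in 3 libraries per group. PK9328 is described in the literature as a ligand of the mutant p53 protein. The series design asks how gene expression differs between DMSO and MS172, and PK9328 is a second compound in the same experiment. The protocol gives 5 µM for 6 h for the drug samples, although it names MS78 where the other labels name MS172. Depth was 24077353 to 28031886 estimated reads per library, and 13914 genes were tested. The first principal component of log2 CPM held 35.6% of the variance and placed the DMSO libraries between those of the compounds. Of 26 ductal and epithelial markers, 19 lay under 1 CPM in every library, among them the adhesion genes EPCAM (at most 0.0745 CPM), CDH1 (0.0417 CPM) and the keratin KRT7 (0.103 CPM). KRT18 and KRT19 stood at 785 and 311 CPM with DMSO, and the mesenchymal genes VIM and COL1A2 at 9390 and 2420 CPM, so the labelled cell type is given here as the label states it.

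**Figure D1:**
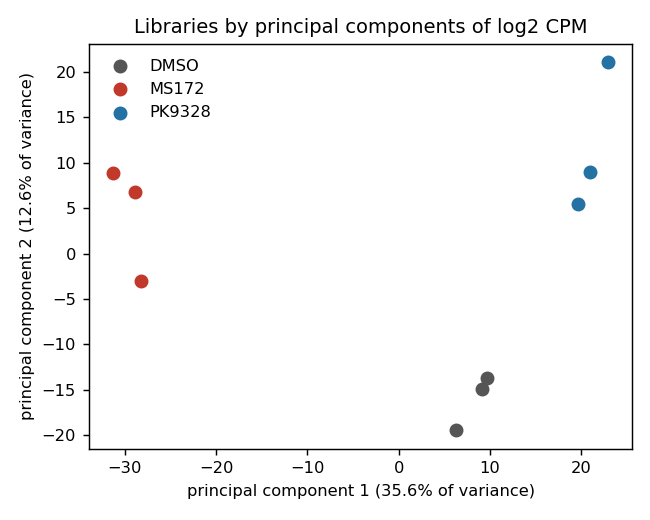
Each point is a library placed by the first and second principal components of log2 CPM, coloured by group. The MS172 libraries lie at -31.24 to -28.23 on the first component, the DMSO libraries at 6.28 to 9.61 and the PK9328 libraries at 19.62 to 22.88.

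With MS172, genes of cholesterol synthesis, metallothioneins, inflammatory chemokines, oxidative stress genes and cytosolic chaperones rose against DMSO. CXCL8, a neutrophil chemokine (chromosome 4, 73740506 to 73743716), rose from 73.8 CPM ± 1.4 to 293 CPM ± 7.7 (SD, n = 3 each), a log2 fold change of 1.99 ± 0.04 (SE, edgeR adjusted p = 5.4e-25). INSIG1, a sterol-responsive regulator of SREBP processing (chromosome 7, 155297776 to 155310235), rose from 53.3 CPM ± 2.3 to 184 CPM ± 6.7, a log2 fold change of 1.79 ± 0.04 (edgeR adjusted p = 2.5e-24). MT1X, a metallothionein that binds zinc (chromosome 16, 56682424 to 56684196), rose from 106 CPM ± 8.0 to 509 CPM ± 38, a log2 fold change of 2.27 ± 0.07 (edgeR adjusted p = 3.4e-10). In all, 4884 genes changed by edgeR, 2486 higher and 2398 lower, of which 49 rose and 174 fell by more than 2-fold. An offset for GC content and length that also set each library's level gave 3769 higher and 1622 lower, whereas its centred form gave 2621 and 2259.

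Of 23 measured cholesterol genes, 20 rose with MS172 (20 adjusted over the list alone), with a median log2 fold change of 0.51 (camera adjusted p = 2.5e-57, and 0.0014 with an estimated correlation). MSMO1 and HMGCS1, enzymes of sterol synthesis, rose by 1.35 and 1.12. Of 9 metal response genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 1.31 (camera adjusted p = 9.8e-31, and 0.0023 with an estimated correlation). The zinc exporter SLC30A1 rose by 0.91, and the zinc importer SLC39A10 was the member that fell, by 0.79. Of 19 NF-kB and cytokine genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 8e-19). CXCL5 rose by 1.37, NFKBIA, the NF-kB inhibitor, by 0.79, and TNFAIP2 fell by 0.28.

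Of 25 NRF2 genes, 16 rose and 1 fell with MS172 (16 and 1 adjusted over the list alone; camera adjusted p = 5.3e-16). HMOX1, which encodes heme oxygenase, rose from 24.1 CPM ± 0.91 to 55.4 CPM ± 1.9, and TXNRD1, a thioredoxin reductase, rose by 1.02. Of 18 heat shock genes, 16 rose and 1 fell (16 and 2 adjusted over the list alone; camera adjusted p = 1.7e-15). HSPA1B and DNAJB1 rose by 0.93 and 0.46, and HSPA6, at 0.755 CPM with DMSO, was the member that fell, by 1.40. Of 30 immediate early genes, 17 rose and 6 fell (18 and 6 adjusted over the list alone; camera adjusted p = 0.0023). NR4A1, a nuclear receptor, rose by 1.23, while EGR1 had a log2 fold change of -0.25.

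Further lists were called higher with MS172 at the preset correlation but not with an estimated one. Ribosomal protein genes rose in 21 of 35 (22 adjusted over the list alone; camera adjusted p = 8.4e-06), with adjusted p = 0.54 with an estimated correlation. Lysosome genes rose in 11 of 27 and fell in 1 (11 and 2 adjusted over the list alone; camera adjusted p = 0.00045), with adjusted p = 0.058 with an estimated correlation. Ductal genes rose in 5 of 8 and fell in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0044), with adjusted p = 0.052 with an estimated correlation, on the 8 of 26 list members that were tested. Integrated stress genes rose in 15 of 30 and fell in 4 (16 and 4 adjusted over the list alone; camera adjusted p = 0.016), with adjusted p = 0.18 with an estimated correlation. Mitotic G2/M genes rose in 9 of 30 (9 adjusted over the list alone; camera adjusted p = 0.035), with adjusted p = 0.18 with an estimated correlation and 0.0545 under the stricter filter.

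The p53 target list was not called by camera with MS172 against DMSO. The list test fry, which does not set members against other genes, called it upward (fry adjusted p = 7.9e-05). Of 53 measured targets 9 rose and 10 fell (9 and 10 adjusted over the list alone), with a median of 0.03 (camera adjusted p = 0.13). With the offset that also set library levels 16 rose and 7 fell, at a median of 0.11 (camera adjusted p = 0.11). That offset also moved the median of all tested genes from -0.02 to 0.05. GDF15, a stress-induced cytokine, rose by 1.03 ± 0.04 (SE), CDKN1A, the cell cycle inhibitor p21, by 0.47 ± 0.08, and BBC3, the pro-apoptotic protein PUMA, by 0.41 ± 0.05. GDF15, CDKN1A and BBC3 are among 7 targets, listed below, that ATF4 or CHOP also activate. MDM2, the p53 ubiquitin ligase, had a log2 fold change of 0.01 (95% interval -0.32 to 0.33, edgeR adjusted p = 0.98), PLK3 fell by 0.36 and PHLDA3 fell by 0.31. The p53 apoptosis genes rose in 5 of 15 (camera adjusted p = 0.13, and fry adjusted p = 0.00028, upward).

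Other genes that rose furthest with MS172 were WNT6, WIPF3, MT1M, MT1E and TXNIP, at log2 fold changes of 2.05, 1.97, 1.72, 1.55 and 1.39, and CKS2, a cyclin-dependent kinase subunit, rose by 1.16. The largest falls were those of CRACDL (-2.65), ZSCAN20 (-1.81), HOXA11 (-1.63), TSSK6 (-1.54), ZNF471 (-1.54), NBPF12 (-1.51), RAD52 (-1.46) and ZNF391 (-1.38). All 8 were at or below 10.7 CPM with DMSO, and CRACDL lost its call when any of the 6 libraries was left out (edgeR adjusted p = 0.074 to 0.11), with the covariate (0.055) and with length-scaled TPM, where it was at -0.63 (edgeR adjusted p = 0.41). MYC had a log2 fold change of 0.00 (95% interval -0.08 to 0.07), EP300 one of 0.15 (edgeR adjusted p = 0.054, and 9.4e-05 to 0.046 in the 8 alternatives that called it), CREBBP one of -0.07 (edgeR adjusted p = 0.38) and CYP1A1 one of -0.53 (edgeR adjusted p = 0.16). FOS was at 0.37 (edgeR adjusted p = 0.048) and lost its call without any of MS172 1, 2 and 3 and DMSO 2 and 3 (edgeR adjusted p = 0.057 to 0.27).

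Against DMSO with MS172, camera gave adjusted p = 0.98 for G1/S genes, 0.42 for unfolded protein genes, 0.13 for interferon genes, 0.092 for hypoxia genes, 0.095 for mitochondrial mRNAs, 0.08 for MAPK feedback genes and 0.98 for ribosome biogenesis genes. It gave 0.57 for acetylation and bromodomain genes, 0.81 for bromodomain inhibitor markers, 0.16 for aryl hydrocarbon receptor targets, 0.94 for replication histones, 0.62 for fibroblast markers and 0.66 for leukocyte markers. For YAP and TGF-beta targets it gave 0.63, where the median of -0.18 and the mean of -0.09 lay below 0 and the test direction was up. The test direction was also up for MAPK feedback genes (median -0.02, mean 0.06), and for hypoxia (median 0.06, mean -0.09), unfolded protein (0.05, -0.06) and replication histone genes (0.17, -0.02), and down for ribosome biogenesis genes (0.01, -0.01). Without DMSO replicate 2 the aryl hydrocarbon receptor, hypoxia and MAPK feedback lists were called (camera adjusted p = 0.041, 0.0438 and 0.0467), and without DMSO replicate 3 the mitochondrial mRNAs (0.000602). Hypoxia and MAPK feedback genes were called also with the centred offset (0.0337 and 0.0362) and the other offset (0.0225 and 0.015), and aryl hydrocarbon receptor targets and mitochondrial mRNAs with length-scaled TPM (0.0357 for each). BNIP3, a hypoxia gene at 0.647 CPM with DMSO, fell by 2.48, and MX1, an interferon-stimulated gene at 1.23 CPM, fell by 0.95.

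**Figure D2:**
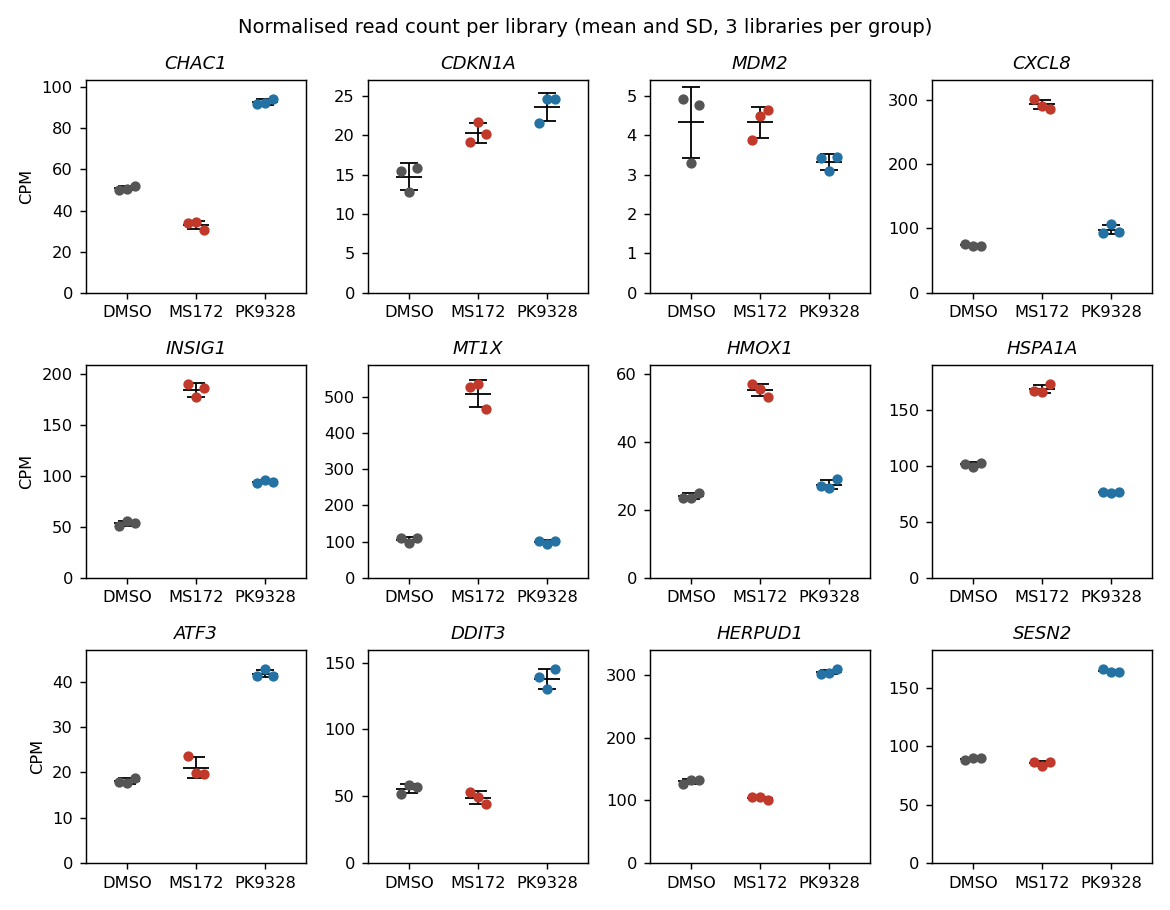
Each point is the CPM of a library, with the mean and SD of 3 libraries as a bar, on axes that start at 0. CXCL8, INSIG1, MT1X, HMOX1 and HSPA1A are highest in the MS172 libraries, and ATF3, CHAC1, DDIT3, HERPUD1 and SESN2 in the PK9328 libraries.

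With PK9328, most genes of the integrated stress response and 6 of 21 unfolded protein genes rose against DMSO. DDIT3, the transcription factor CHOP (chromosome 12, 57516588 to 57521737, minus strand), rose from 55.6 CPM ± 3.4 to 138 CPM ± 7.7 (SD, n = 3 each), a log2 fold change of 1.31 ± 0.06 (SE, edgeR adjusted p = 1.7e-10). HERPUD1, a protein of endoplasmic reticulum degradation (chromosome 16, 56932048 to 56944863), rose from 130 CPM ± 3.5 to 305 CPM ± 3.6, and DNAJB9, an endoplasmic reticulum chaperone, from 22.3 CPM ± 2.0 to 52.3 CPM ± 0.81. ATF3, a stress-induced transcription factor (chromosome 1, 212565334 to 212620777), rose from 18.1 CPM ± 0.61 to 41.8 CPM ± 0.83. In all, 2151 genes changed by edgeR, 1110 higher and 1041 lower, of which 23 rose and 9 fell by more than 2-fold.

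The PK9328 libraries also differed in fragment length, estimated at 249.5 to 263 bases against 281.2 to 289.1 with DMSO and 274.1 to 292.8 with MS172. With fragment length as a covariate 178 genes changed, and with length-scaled TPM 1066. All PK9328 libraries had shorter fragments than all others, so the covariate overlaps with the group and widens the errors of its folds. A call lost with the covariate does not by itself show that fragment length accounts for the change. Without DMSO replicate 1 the count was 1384, and without PK9328 replicate 2 it was 1400. An offset that also set each library's level gave 990 higher and 1473 lower, and its centred form 1219 and 1103.

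Of 30 integrated stress genes, 25 rose with PK9328 (26 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 5.5e-97, and 4e-04 with an estimated correlation). With the fragment length covariate 17 rose, at a median of 0.39 (camera adjusted p = 9.3e-51). SESN2 rose by 0.88, TRIB3, a pseudokinase induced by ATF4, by 0.76, CHAC1 by 0.87 and ATF4 itself by 0.46. Of 21 unfolded protein genes, 6 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 5.8e-16), with a median of 0.09, and 5 rose and 1 fell with the covariate, at a median of 0.04 (camera adjusted p = 6.3e-08). HSPA5, the chaperone BiP, rose by 0.52, while HSP90B1 fell by 0.20 and CRELD2 fell by 0.21. Of 23 cholesterol genes, 14 rose (16 adjusted over the list alone; camera adjusted p = 6.8e-22), with a median of 0.24, and 5 rose with the covariate, at a median of 0.19 (camera adjusted p = 2.1e-13). INSIG1 rose by 0.83 ± 0.04 (SE) and MSMO1 by 0.71.

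The p53 target list was called higher with PK9328. Of 53 measured targets 15 rose (18 and 2 lower adjusted over the list alone), with a median of 0.08 (camera adjusted p = 4e-11), and 5 rose with the fragment length covariate, at the same median (camera adjusted p = 9.2e-08). CDKN1A rose from 14.7 CPM ± 1.7 to 23.6 CPM ± 1.8 (SD, n = 3 each), and BBC3 and GDF15 rose by 0.72 and 0.74. GADD45A, PMAIP1 and PPM1D rose by 0.72, 0.52 and 0.45. Of the genes just named, all but PPM1D are among the 7 targets, listed below, that ATF4 or CHOP also activate. Those 7 had a median of 0.72, and the other 46 targets one of 0.03. BBC3 and PMAIP1 are also members of the p53 apoptosis list. MDM2 had a log2 fold change of -0.38 (95% interval -0.70 to -0.05, edgeR adjusted p = 0.11), and without DMSO replicate 2 one of -0.55 (edgeR adjusted p = 0.019). The p53 apoptosis genes rose in 4 of 15 and fell in 1 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0026), with a median of 0.01, and 1 rose with the covariate, at a median of 0.05 (camera adjusted p = 0.011).

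Cell cycle genes were lower with PK9328. Of 28 G1/S genes, 14 fell (19 adjusted over the list alone; camera adjusted p = 2.2e-10), with PCNA, the replication clamp, at -0.28 and MCM2 at -0.27. Of 30 G2/M genes, 13 fell (16 adjusted over the list alone; camera adjusted p = 7.3e-08), with MKI67, a proliferation marker, at -0.31. The list medians were -0.16 and -0.11 in these libraries of shorter fragments, and -0.16 and -0.10 with the covariate, under which the 14 and 13 members lost their edgeR calls while camera gave adjusted p = 7.8e-06 and 0.0023. Of 18 heat shock genes, 10 fell and 1 rose (11 and 2 adjusted over the list alone; camera adjusted p = 2.1e-06), with HSPA1A at -0.41 and HSPA8 at -0.30. The heat shock median was -0.13, and with the covariate 2 fell, at a median of -0.09 (camera adjusted p = 0.00082).

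NF-kB genes rose in 9 of 19 and fell in 1 with PK9328 (9 and 1 adjusted over the list alone; camera adjusted p = 2.2e-05), with CXCL8 at 0.41 and CXCL2 at 0.58. Immediate early genes rose in 11 of 30 and fell in 2 (14 and 3 adjusted over the list alone; camera adjusted p = 8.7e-06). Aryl hydrocarbon receptor targets rose in 4 of 9 (4 adjusted over the list alone; camera adjusted p = 0.00054). The members that rose were SLC7A5, EREG, NFE2L2 and TIPARP, whereas CYP1A1, the receptor's usual marker, was at -0.14 (edgeR adjusted p = 0.81). SLC7A5 is also a member of the integrated stress list, as is ATF3 of the immediate early genes, so these lists overlap with it. Hypoxia genes rose in 6 of 22 and fell in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0046), with VEGFA at 0.82. With the covariate, 2 NF-kB, 5 immediate early, 2 aryl hydrocarbon receptor and 2 hypoxia genes rose, at list medians of 0.09, 0.25, 0.23 and 0.08 (0.17, 0.16, 0.21 and 0.09 without it), and camera still called the 4 lists.

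Further lists were called with PK9328 at the preset correlation but not with an estimated one. Interferon genes fell in 4 of 21 and rose in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.014), with adjusted p = 0.064 with an estimated correlation. YAP and TGF-beta targets fell in 5 of 16 (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0044), with adjusted p = 0.064 with an estimated correlation, 0.0706 with the covariate, and a mean of 0.02 above 0 beside a median of -0.06. Fibroblast markers fell in 2 of 5 (2 adjusted over the list alone; camera adjusted p = 0.0055), with adjusted p = 0.058 with an estimated correlation, and the mean of 0.05 beside a median of -0.20 went with ACTA2 at 1.22 (edgeR adjusted p = 0.32). Mitochondrial mRNAs had a median of -0.27 (camera adjusted p = 0.048), with adjusted p = 0.74 with an estimated correlation, and lost their call without DMSO 3 (0.474), PK9328 2 (0.298) or PK9328 3 (0.121). Ribosomal protein genes rose in 2 of 35 and fell in 1 (1 higher adjusted over the list alone; camera adjusted p = 0.035), with adjusted p = 0.76 with an estimated correlation, lost their call without DMSO 2 (0.439) or PK9328 3 (0.568), and were lower with the fragment length covariate (0.000657).

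Other genes that rose furthest with PK9328 were FSBP, KLHDC7B, IL21R and INHBE, at 1.91, 1.62, 1.28 and 1.26, and the first 3 lost their call with the covariate. FSBP and KLHDC7B were then at 0.50 and 0.84 (edgeR adjusted p = 0.87 and 0.6), and IL21R at 1.06 (edgeR adjusted p = 0.1). The largest falls were those of TMEM200B (-1.13), TMOD1 (-1.03), NANOS1 (-0.82), H1-2 (-0.70), PTGFRN (-0.67), C14orf28 (-0.67), KCNJ14 (-0.60) and ISLR (-0.54). All 8 were at or below 5.66 CPM with DMSO. All 8 lost their call with the covariate, at folds of -0.65, -0.86, -1.19, -0.98, -0.63, -0.76, -0.82 and -0.78 in the same order. With single libraries left out NANOS1, H1-2, PTGFRN, C14orf28, KCNJ14 and ISLR lost theirs in 4, 2, 3, 4, 1 and 5 of 6 cases (edgeR adjusted p = 0.058 to 0.15). HMOX1 rose by 0.19 and CREBBP by 0.19, and with the covariate they were at 0.04 and 0.22 (edgeR adjusted p = 0.92 and 0.43). HMOX1 lost its call also without DMSO 1, DMSO 2 or PK9328 3 (edgeR adjusted p = 0.084, 0.069 and 0.13) and CREBBP without DMSO 3 or PK9328 2 (0.12 and 0.16). MYC was at 0.07 (95% interval 0.00 to 0.15), EP300 at 0.08 (edgeR adjusted p = 0.4) and FOS at 0.31 (edgeR adjusted p = 0.15, and 0.026 without DMSO replicate 1), and EGR1 rose by 0.20.

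Against DMSO with PK9328, camera gave adjusted p = 0.94 for metal response genes, 0.62 for NRF2 genes, 0.88 for lysosome genes, 0.57 for MAPK feedback genes, 0.066 for ribosome biogenesis genes and 0.81 for acetylation and bromodomain genes. It gave 0.81 for bromodomain inhibitor markers, 0.88 for replication histones, 0.084 for ductal genes and 0.62 for leukocyte markers. Ribosome biogenesis genes were called lower without DMSO 2 (0.0203) or PK9328 3 (0.0289). The test direction was up while the median lay below 0 for metal response (median -0.02, mean 0.03), NRF2 (-0.05, 0.04) and lysosome genes (-0.04, 0.02), and down for replication histones (0.04, 0.03).

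**Figure D3:**
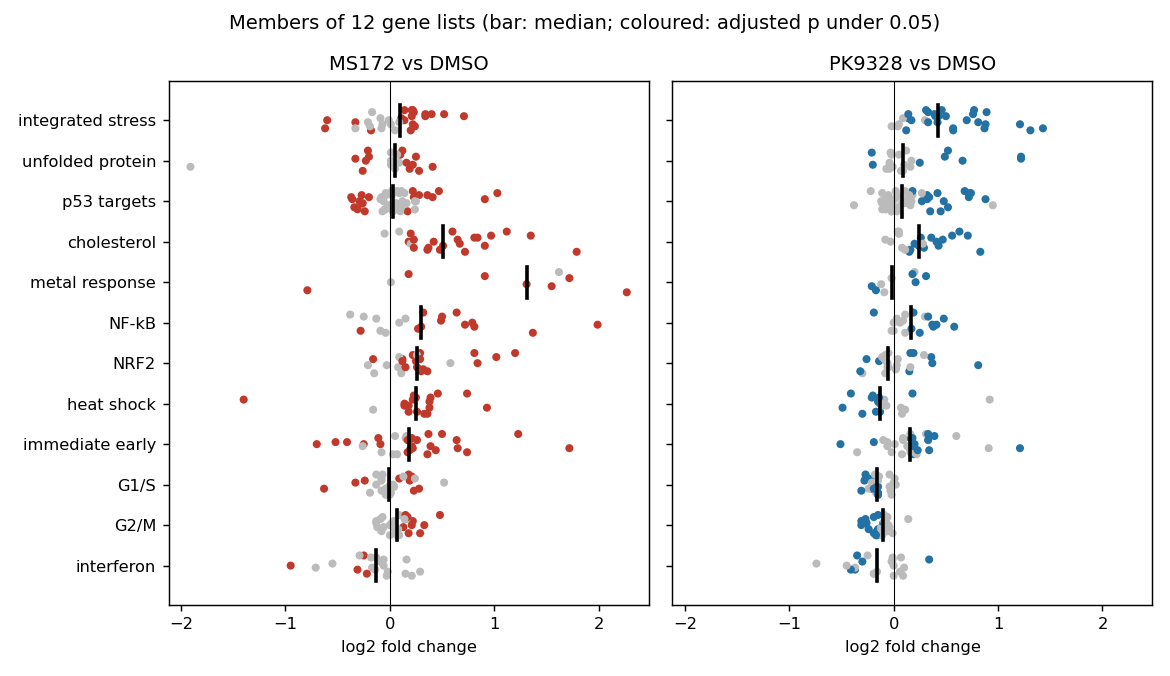
Each point is the log2 fold change of a list member, for MS172 and for PK9328 against DMSO, coloured where the adjusted p was under 0.05, with a bar at the list median. The integrated stress median is 0.10 with MS172 and 0.42 with PK9328, and the metal response median is 1.31 and -0.02.

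Compared with PK9328, MS172 gave higher metallothioneins, heat shock chaperones, cholesterol genes and G2/M genes and lower integrated stress genes. The endoplasmic reticulum chaperones HSPA5 and DNAJB9 were also lower with MS172 (-0.40 and -1.42). The protocol gives the same dose and time for PK9328 and MS78 and does not name MS172, so an equal dose was not certain. HERPUD1 was lower with MS172 by a log2 fold change of -1.55 ± 0.04 (SE), CHAC1 by -1.49 ± 0.05 and PPP1R15A, a phosphatase subunit induced by ATF4, by -1.31 ± 0.04. MT1X was higher by 2.36 ± 0.07, CXCL8 by 1.58 ± 0.04, CCN1, a YAP target, by 1.51 ± 0.05 and HSPA1A by 1.15 ± 0.04. In all, 6641 genes differed by edgeR, 3240 higher and 3401 lower with MS172. With fragment length as a covariate 2480 differed. An offset that also set each library's level gave 4565 higher and 2371 lower, and its centred form 3264 and 3272.

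Integrated stress genes were lower with MS172 than with PK9328 in 19 of 30 and higher in 3 (19 and 3 adjusted over the list alone; camera adjusted p = 9.3e-19). DDIT3 differed by -1.49 and ATF3 by -0.99. Metal response genes were higher in 5 of 9 and lower in 2 (5 and 2 adjusted over the list alone; camera adjusted p = 2.8e-19). Heat shock genes were higher in 16 of 18 and lower in 2 (16 and 2 adjusted over the list alone; camera adjusted p = 2.8e-19). Cholesterol genes were higher in 17 of 23 and lower in 1 (17 and 1 adjusted over the list alone; camera adjusted p = 1.8e-13), with INSIG1 at 0.96 and MSMO1 at 0.64. NRF2 genes were higher in 17 of 25 and lower in 1 (18 and 1 adjusted over the list alone; camera adjusted p = 1.5e-09), with HMOX1 at 1.01 and SLC7A11, the cystine transporter, at -1.02.

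G2/M genes were higher with MS172 than with PK9328 in 20 of 30 (20 adjusted over the list alone; camera adjusted p = 3e-06), with PTTG1 at 0.64. NF-kB genes were higher in 9 of 19 and lower in 5 (9 and 5 adjusted over the list alone; camera adjusted p = 3.7e-06). Ductal genes were higher in 5 of 8 and lower in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0011), with the tight junction gene CLDN4 at 1.05. G1/S genes were higher in 19 of 28 and lower in 1 (19 and 2 adjusted over the list alone; camera adjusted p = 0.0012), with adjusted p = 0.054 with an estimated correlation. Unfolded protein genes were higher in 9 of 21 and lower in 9 (9 and 10 adjusted over the list alone; camera adjusted p = 0.00096, downward), with adjusted p = 0.18 with an estimated correlation and a median of 0.02 beside a mean of -0.27. With the covariate, 8 of 30 G2/M, 4 of 28 G1/S and 3 of 8 ductal genes were higher and 12 of 30 integrated stress genes lower, at list medians of 0.16, 0.15, 0.26 and -0.19 (0.18, 0.19, 0.30 and -0.24 without it), and camera still called these 4 lists.

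The p53 targets were lower with MS172 than with PK9328 in 22 of 53 and higher in 9 (23 and 10 adjusted over the list alone; camera adjusted p = 0.042), with adjusted p = 0.073 with an estimated correlation, 0.114 with length-scaled TPM, 0.0576 with the covariate (8 lower and 3 higher, at a median of -0.10 against -0.11 without it) and 0.059 without MS172 replicate 3. With the offset that also set library levels 16 were lower and 14 higher, at a median of 0.00 (camera adjusted p = 0.0732), so the call was lost there. That offset also moved the median of all tested genes from -0.03 to 0.06. SESN2 differed by -0.95, PPM1D by -0.69 and BBC3 by -0.31 ± 0.05 (SE). GDF15 was higher with MS172 by 0.29 ± 0.04. CDKN1A differed by -0.21 (95% interval -0.38 to -0.05, edgeR adjusted p = 0.026), and MDM2 by 0.38 (95% interval 0.06 to 0.71, edgeR adjusted p = 0.049). CDKN1A lost its call without any of MS172 1 and 3 and PK9328 2 and 3 (edgeR adjusted p = 0.068 to 0.13), and MDM2 without any of the 5 libraries MS172 2 and 3 and PK9328 1, 2 and 3 (edgeR adjusted p = 0.065 to 0.15). MDM2 lost it also with DESeq2 (adjusted p = 0.08) and limma-voom (adjusted p = 0.077). In edgeR, MDM2 lost it with no filter (edgeR adjusted p = 0.068), the stricter filter (0.051), the replicate block (0.057), length-scaled TPM (0.56) and the covariate (0.72). CDKN1A lost its call with DESeq2 (adjusted p = 0.077), and in edgeR with length-scaled TPM (0.078) and the covariate (0.26). BBC3 lost its call with the covariate (edgeR adjusted p = 0.058). MYC differed by -0.08 (95% interval -0.15 to 0.00, and edgeR adjusted p = 0.022 without PK9328 replicate 1), EP300 by 0.07 (95% interval -0.05 to 0.19) and CYP1A1 by -0.39 (95% interval -0.98 to 0.20).

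Between the compounds, lists whose call was lost with an estimated correlation were lysosome genes (camera adjusted p = 0.008), with adjusted p = 0.14 with an estimated correlation, and mitochondrial mRNAs (0.015), with adjusted p = 0.69 with an estimated correlation. Ribosomal protein genes (0.028) had adjusted p = 0.75 with an estimated correlation, fibroblast markers (0.05) had adjusted p = 0.15, and YAP and TGF-beta targets (0.05) had adjusted p = 0.16 with an estimated correlation. For YAP and TGF-beta targets the test direction was up while the median was -0.13 and the mean -0.11, and it was down for hypoxia genes (median 0.02, mean -0.17) and up for interferon (0.06, -0.01) and replication histone genes (0.08, -0.05). The ribosomal protein call was lost without any of MS172 1 and 2 and PK9328 1 and 2 (0.064 to 0.0956), the fibroblast call without any of MS172 1 and 2 and PK9328 2 and 3 (0.0533 to 0.0662), and the YAP and TGF-beta call without any of MS172 3 and PK9328 2 and 3 (0.0547 to 0.0785). The largest falls against PK9328 were those of FSBP (-2.62), NBPF12 (-2.24), RAD52 (-2.19), TSSK6 (-2.14), H4C14 (-2.03) and MIA-RAB4B (-1.96), of which FSBP and MIA-RAB4B lost their call with the covariate, at -1.20 and -0.96 (edgeR adjusted p = 0.39 and 0.13). Camera gave adjusted p = 0.55 for acetylation and bromodomain genes, 0.6 for aryl hydrocarbon receptor targets, 0.74 for bromodomain inhibitor markers, 0.94 for hypoxia genes, 0.94 for immediate early genes and 0.97 for interferon genes. It gave 0.37 for MAPK feedback genes, 0.4 for ribosome biogenesis genes, 0.55 for leukocyte markers, 0.81 for p53 apoptosis genes and 0.88 for replication histones.

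The responses to the compounds were compared across genes. Both compounds raised INSIG1 and GDF15, whereas CHAC1 and HERPUD1 rose with PK9328 and fell with MS172 (-0.62 and -0.33). Of genes called in both comparisons, 268 rose with both (198.3 for independent lists), 102 fell with both (179.4), 389 rose with MS172 and fell with PK9328 (186) and 320 fell with MS172 and rose with PK9328 (191.3). Across 13914 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.249 and a Spearman correlation of -0.0413. Unchanged groups simulated against shared controls gave 0.501 and 0.445 on average in 100 simulations. These simulated groups held no response. Responses in unlike genes would also lower a correlation or a same-sign share, so only the covariances are comparable. The covariance was 0.0348 against a simulated 0.0407, a difference of -0.00599, and 45.9% of genes had the same sign against a simulated 66.6%. The correlation was 0.415, 0.414 and 0.404 without DMSO replicate 1, 2 or 3 (simulated alike 0.595, 0.603 and 0.593), 0.0966 with the stricter filter (0.491), 0.0977 with the covariate (0.133) and 0.119 with log CPM differences (0.502). The covariance differences of the first 5 were 0.0234, 0.0213, 0.0178, -0.0102 and 0.00187. Log CPM differences gave -0.0107 (simulated SD 0.00202), and the simulated SD beside the main difference of -0.00599 was 0.00698. The sign varied with the setting, so the sign of the shared part was not settled. The 3 DMSO libraries were not split, since a part would hold 1 library. Their chance values move both fold changes the same way, so part of any overlap in the same direction may come from them.

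**Figure D4:**
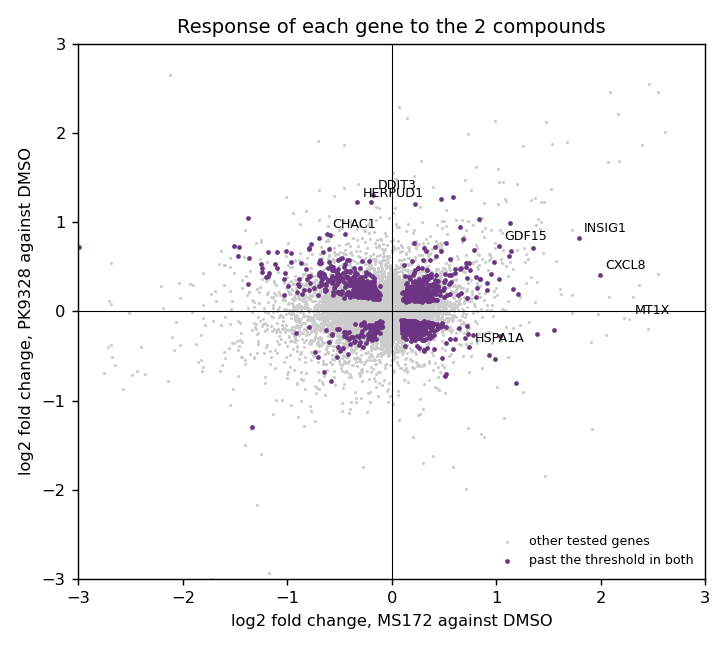
Each point is a gene, with its log2 fold change with MS172 on the horizontal axis and with PK9328 on the vertical axis, both against DMSO. The 1079 genes past the threshold in both comparisons are coloured and lie in all 4 quadrants, and 25 genes beyond 3 or -3 are not drawn.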

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

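The tests of the decay isoforms below were chosen after the library-level shares had been seen, and the rule for calling them was made stricter, by adding the spread between libraries, after a first reading of the values. Measures outside the gene-level comparison lay above or below all 3 DMSO libraries in all 3 PK9328 libraries, which with 3 against 3 cannot give an exact permutation p below 0.1. Transcripts annotated as targets of nonsense-mediated decay held 2.02% of reads with PK9328 and 1.82% with DMSO. Processed transcripts held 1.31% and 1.199%, and retained-intron transcripts 1.61% and 1.52%. Transcript length minus effective length averaged 257.9 bases with PK9328 and 285.1 with DMSO.

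Within genes, the log2 ratio of decay isoforms to coding isoforms was higher with PK9328 by a median of 0.15 over 1136 genes, although limma called no single gene (140 had an unadjusted p under 0.05). With fragment length as a covariate the median was 0.031, and over library medians the difference went from 0.164 ± 0.037 (SE, 9 libraries) to 0.012 ± 0.029, so shorter fragments are a candidate explanation. The ratio for retained-intron isoforms was higher by a median of 0.058 over 1105 genes (0.074 ± 0.03 over library medians), too close to the bound for its spread to decide whether unspliced RNA of all kinds rose. Fragment length follows the groups, so an effect of PK9328 on these isoforms stays open.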

How the results depend on the processing

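The covariate, both offsets and the log CPM measure were chosen after seeing the data, and the cause of each shift below was not tested. With PK9328, 1066 genes changed with length-scaled TPM and 178 with fragment length as a covariate, which shared 918 and 154 with the 2151 reported. Between the compounds 2480 differed with the covariate. Fragment length overlaps with the PK9328 group, so calls can be lost with the covariate while folds stay. Left-out libraries gave 3874 to 4453 genes for MS172, 1384 to 2215 for PK9328 and 5651 to 6150 between the compounds. The other alternatives stayed within 1.5 times of each count. The offset that also set library levels moved the share of higher calls from 50.9% to 69.9%, from 51.6% to 40.2% and from 48.8% to 65.8%, and the centred offset, made after this was seen, gave 53.7%, 52.5% and 49.9%.

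Of 81 list tests 44 were called, 26 with an estimated correlation, 55 with fry, 74 with fry in either direction and 40 to 47 with a library left out. The correlation of the responses, 0.249, was 0.097 with the stricter filter (simulated 0.491), 0.098 with the covariate (0.133), 0.119 with log CPM differences (0.502) and 0.234 to 0.415 with a library left out (0.44 to 0.603). The simulated groups held no response, so their correlations are not those of unrelated responses. Ribosomal protein genes with PK9328 turned downward with the covariate (adjusted p = 0.000657). With length-scaled TPM, HDAC2 was at -0.056 for MS172 against DMSO and HDAC1 at -0.047 between the compounds. With the covariate RPS20 was at -0.001 and RPS2 at 0.082 with PK9328, and RPS2 at -0.002 between the compounds. Of 360 values of named genes, 89 lost their call at the same sign with the covariate and 39 with length-scaled TPM. A further 3 and 2, those named above, lost their call with the sign reversed.

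The replicate numbers did not pair the samples. Residual correlations of same-numbered libraries were -0.057 to 0.017, and 1 of 9 libraries correlated best with its own number. With the replicate block 4597, 1884 and 6405 genes changed, 42 list tests were called and the correlation was 0.245. At this depth the simulated recovery of 1.2-fold changes was 46% for MS172 against DMSO, 58.3% for PK9328 against DMSO and 64% between the compounds. The simulated data held far fewer changed genes than the real comparisons, so these shares do not carry over. Small changes can still be missed.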

Other observations

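The families in this part were picked after their values were seen, and so was the test of the p53 targets. The 3 tests of the zinc finger genes were set down after the family's fall was seen but before their own results, except that the centred form of the offset was made later. Among 397 coding genes with ZNF symbols, mostly DNA-binding repressors, 201 fell and 15 rose with MS172 against DMSO, with a median log2 fold change of -0.32. With PK9328, 53 rose and 3 fell, with a median of 0.11, but with fragment length as a covariate 1 rose, with a median of 0.13. Library medians against the DMSO mean were -0.338 to -0.296 with MS172 and 0.096 to 0.127 with PK9328. Of 23 small nucleolar RNA host genes (SNHG), 9 fell and 1 rose with MS172, and 10 rose with PK9328. All 1779 noncoding genes and pseudogenes had medians of -0.16 with MS172 (273 fell and 74 rose) and 0.05 with PK9328. In the main fit the family median was thus no lower with MS172 than this background, although a larger share of the family fell. The difference was not tested. SNHG1 was at -0.66 and 0.67, and SNHG17 at -1.19 and 0.66. The medians of -0.10 and 0.34 kept their signs with RLE factors, length-scaled TPM, both offsets and the covariate, but not their sizes. The MS172 median was -0.22 with the centred offset, and the PK9328 median was 0.19 with length-scaled TPM (6 rose) and 0.17 with the covariate (2 rose).

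The tables argue against 3 technical explanations as the whole cause of the zinc finger fall with MS172. After the centred offset for GC content and length the family median was -0.30, and it was -0.24 with the offset that also set library levels. In 10000 lists of other coding genes matched on expression the typical median was -0.08 and the lowest was -0.14. No list was as low as the family in the main fit, at -0.32. The lists drew genes rather than libraries, so they do not measure chance differences between the libraries. The 126 members whose counts lay within 0.01 of a whole number in every library, as counts split between paralogs mostly do not, had a median of -0.36. An effect of MS172 on these genes may therefore be proposed as a hypothesis, found and tested on the same data.

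BxPC3 is generally described as an epithelial line, whereas the epithelial adhesion genes CDH1 and EPCAM lay at or below 0.0417 and 0.0745 CPM in all 9 libraries and VIM stood at 9390 ± 185 CPM (SD, n = 3) with DMSO. KRT8, KRT18 and KRT19 stood at 732, 785 and 311 CPM and CLDN4 at 122 CPM, and of the fibroblast genes COL1A2 stood at 2420 CPM but COL1A1 at 1.41 CPM. The markers were thus mixed, in all 3 groups alike, and the identity of the line was not tested here.

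The higher p53 target list with PK9328 could reflect targets that ATF4 or CHOP also activate. The 7 targets so listed (SESN2, GDF15, BBC3, GADD45A, PMAIP1, TNFRSF10B and CDKN1A) all rose, with a median of 0.72. Among the other 46 targets 8 rose, with a median of 0.03. Camera on that remainder gave p = 0.012, and 0.023 with an estimated correlation. The remainder was still called but with a median near 0, so whether these 7 targets account for the call stays open.

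Relabelling the 6 libraries of each comparison gives 10 splits, too few for a share under 0.05. As many genes were given by 1 of 10 splits in each comparison, the real one. It gave 4730 genes for MS172 against DMSO (highest other split 0), 2140 for PK9328 against DMSO (4) and 6757 between the compounds (1).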
